A study of Danio rerio with 10 samples.

How the data were processed

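RNA of whole zebrafish embryos at the 17 to 18 somite stage was sequenced from 5 wild-type (ABTU) and 5 tpcn2 mutant samples, 1 library each. Embryos were kept at 28 °C and RNA was extracted with RNAzol, per the labels' protocols. Reads were trimmed with cutadapt 3.4 and aligned with STAR 2.7, per the submitters' processing notes, which also name DESeq2 1.30.0 and the builds danRer10 and mm10 without saying what each was used for. The program that counted reads, its annotation and its strand setting are not given in the sources used here. Without strand, reads of a gene and an overlapping antisense gene cannot be told apart.

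The deposited table holds raw counts per gene symbol for the 10 libraries, whole numbers that sum to a different total in each library. It has 14650 genes, of which 522 have no count in any library. A second table, the authors' own comparison, holds log2 fold changes, p-values and adjusted p-values (unit and direction per the file headers and the sign of tpcn2) and a score, the test statistic, for 14005 genes; 545 of them have no adjusted p. In that deposited table the log2 fold change equals the statistic times its error within 1% for 94.2% of genes. This check does not show how the log2 fold changes were estimated. The authors' deposited table also gives a signal, the mean of counts divided by size factors over all libraries per the file headers, which served no test here.

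Counts were analysed as deposited. Libraries were grouped by the genotype in their labels. Genes were kept by edgeR's filterByExpr (11871 of 14650), scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with genotype as the single term and Benjamini-Hochberg adjustment over all tested genes; the threshold was 0.05. CPM values are TMM-scaled. Standard errors are those of the difference of mean log2 CPM with a prior count of 2, from the spread of the 5 libraries in each group. A fold against a group with no reads was taken against 3 counts per library (0.133 to 0.168 CPM), and with 1 to 3 reads an exact 95% interval of the ratio of reads is given. These cover counting error only and leave out the spread between libraries. They also treat each read as a separate count, although reads were not counted by molecular identifiers.

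The pipeline was tested on simulated counts drawn from the means and dispersions of the 11720 genes tested there, with 200 genes changed and 1 list moved by 0.3 on the log2 scale. For the comparison of mutant with wild type, 10% of the genes changed by 0.25 (log2) were recovered, 69.4% at 0.5, 93.9% at 1 and 100% at 2, and 10 of 145 calls were false (6.9%). The data gave 5011 calls, far more than the simulation, so the adjustment placed the cutoff at another p-value there. These recovered and false shares therefore do not carry over to the data. The moved list, slow muscle fibre and muscle pioneer, had an adjusted p of 1.46e-10 by camera and 0 other lists were called. Simulated genes varied independently, whereas members of that list had an estimated correlation of 0.282 in the real data. The simulation therefore cannot show how often camera calls lists of correlated genes falsely.

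29 gene lists were fixed before the data were examined, together with the tests, the groups and the rule for the genes named. Of 968 list members, 825 were matched to the count table, 42 of them by an older symbol. 14366 of 14650 symbols (98.06%) matched the RefSeq gene table of the GRCz12tu assembly, 12548 by symbol and 1818 by synonym. That assembly differs from the builds in the processing notes, so it was used for names and gene order alone, and 11671 of the tested genes had an order. The planned window in base pairs around tpcn2 was replaced by the 50 nearest tested genes on each side, a choice made after the data were examined.

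Lists with at least 5 tested members were tested with limma 3.58.1: camera on log2 CPM with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists. Named genes were the two-pore channel genes, then, among genes past 0.05 with a mean of at least 1 CPM and all libraries of one group above those of the other, the 10 largest and 10 smallest log2 fold changes with symbols that are not clone names, and the 5 most abundant in each direction with an absolute log2 fold change of at least 0.5. For each list up to 3 members past 0.05 in each direction were named, smallest p first; 2 genes so chosen are not reported here. Exact permutation tests enumerated all splits, and differences of medians used 100000 permutations (scipy 1.17.1, Python 3.11.15). Fisher's exact test was two-sided. Adjacent pairs of genes changed at least 2-fold were compared with 10000 permutations of labels within 10 expression deciles.

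Alternatives were RLE size factors, library size without scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean CPM of at least 1, the replicate number as a block, gene lists without genes of more than 1 list, a stricter threshold of 0.01, glmTreat against a log2 fold change of 1, and leaving out each library in turn. The 10 libraries can be split in 126 ways into 5 and 5, of which 100 were refitted.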

Results

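Whole zebrafish embryos at the 17 to 18 somite stage, grown at 28 °C, were profiled by RNA-seq in 2 groups: wild type of the ABTU strain and a tpcn2 mutant, which the series' design text says have 5 biological replicates each. The sources used here do not say whether replicates are separate clutches or whether the wild type are siblings of the mutants. Differences between the groups below therefore cannot be told apart from those of strain background or clutch. tpcn2 encodes two-pore channel 2, a cation channel of the lysosome membrane that releases calcium. At this stage somites are still forming and slow muscle of the trunk is starting to differentiate, and the series title names trunk development as its subject. Total counts per library lay between 17890367 and 22498643, with means of 20059586 ± 1615092 in wild type and 19678753 ± 1669852 in the mutant (SD, n = 5). The 10 most abundant genes took 8.22 to 8.53% of counts in wild type and 8.53 to 8.75% in the mutant, and krt4, a keratin of the outer epithelium, led every library.

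tpcn2 itself was lower in every mutant library. It was at 58.0 ± 14 CPM in wild type and 9.28 ± 1.56 CPM in the mutant (SD, n = 5), a log2 fold change of -2.64 ± 0.186 (SE), or 0.16 times the wild-type level. The 5 wild-type libraries lay between 47.1 and 81.1 CPM and the 5 mutant libraries between 6.72 and 10.3 CPM. edgeR's quasi-likelihood test gave an adjusted p of 3.19e-08 and an exact two-sided permutation test of log2 CPM gave p = 0.00794, the smallest that 5 against 5 libraries allow. Between 146 and 215 tpcn2 reads remained in each mutant library, so the transcript was reduced and not lost. tpcn3, listed under its older symbol gb:eh507706, was at 7.62 ± 1.16 CPM in wild type and 8.47 ± 0.552 CPM in the mutant and did not pass (edgeR adjusted p = 0.328), and tpcn1 was not analysed here.

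**Figure D1:**
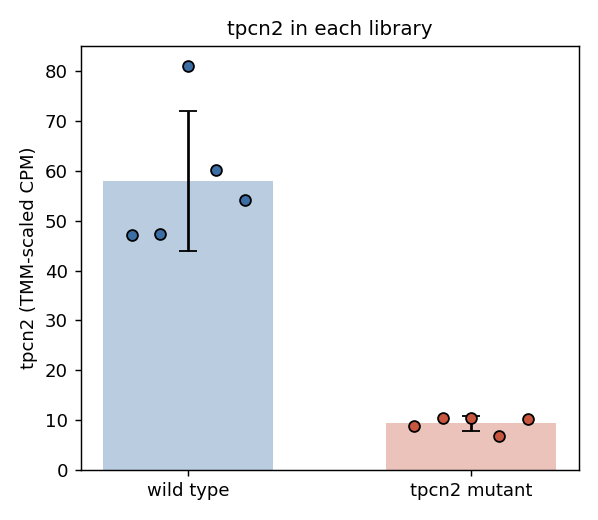
TMM-scaled CPM of tpcn2 in each library, with wild type and tpcn2 mutant on the horizontal axis, points for libraries, bars for group means and error bars for the SD (n = 5). The mutant libraries lie between 6.72 and 10.3 CPM, all below the lowest wild-type library at 47.1 CPM.

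The genotypes differed over a large part of the transcriptome, mostly by small amounts. Of 11871 genes tested, 2442 were higher and 2569 lower in the mutant (edgeR, adjusted p under 0.05), which is 42.2% of the genes. Of these, 301 higher and 373 lower genes changed at least 2-fold, while 58.9% of the called genes changed by less than 0.5 on the log2 scale. The libraries of one group lay entirely above those of the other for 3405 genes, against 0.794% of genes by chance. The first principal component held 57.1% of the variance and separated the genotypes, and correlations of log2 CPM across genes were 0.964 to 0.970 between genotypes against 0.981 to 0.992 within them. The second component, with 10.1% of the variance, set wild-type replicate 1 (score 33.3) apart from the other wild-type libraries (-17.0 to -0.71). Against a log2 fold change of 1 as the null, edgeR's glmTreat called 89 higher and 128 lower genes.

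The genes that fell furthest in the mutant include enzymes, a lysosomal protease and an opsin. apip, an enzyme of the methionine salvage pathway, was at 74.3 ± 7.33 CPM in wild type and 0.182 ± 0.112 CPM in the mutant. cyp4v7, a cytochrome P450, had 262 reads in the wild-type libraries and 0 in the mutant libraries, at least 15.4-fold lower against a floor of 3 counts per library. sc:d217 had 332 reads in wild type and 1 in the mutant, a ratio of 326 (95% exact interval 58.1 to 12903, counting error only). ctsc, which encodes the lysosomal protease cathepsin C, fell from 1938 ± 585 to 110.6 ± 10.4 CPM (log2 fold change -4.13 ± 0.229), and gsnb, a gelsolin that severs actin filaments, from 104 ± 7.46 to 4.43 ± 0.689 CPM. The other genes of the 10 largest decreases were znf1005 (-5.37), the melanopsin gene opn4b (-4.89), the fucosyltransferase gene fut9d (-4.85), cidec (-4.34) and the complement factor gene bfb (-3.52), given as log2 fold changes. cyp4v7, fut9d and znf1005 belong to families of similar genes, among which reads may be split.

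The largest increases were in genes of differing functions. scn12aa, a voltage-gated sodium channel gene, was at 8.16 ± 1.35 CPM in the mutant and 0.109 ± 0.127 CPM in wild type (log2 fold change 6.14 ± 0.418). wbp1lb rose from 6.95 ± 1.86 to 66.2 ± 7.67 CPM. irg1l, related to an immune-responsive gene of macrophages, rose from 4.33 ± 1.78 to 54.3 ± 60.7 CPM, a mean carried by mutant replicates 2 and 3 (148 and 83.1 CPM, against 8.34 to 17.0 CPM in the other mutant libraries). Other increases were those of the protocadherin gene pcdh1g1 (4.26), ugt1b6p (4.11), the sulfotransferase gene sult2st3 (3.39), sphkap (3.37), mlpha (3.26), which encodes the melanosome transport protein melanophilin, and the MHC class II gene mhc2dbb (3.22), as log2 fold changes. pcdh1g1, ugt1b6p and mhc2dbb have close paralogs.

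Of abundant transcripts, apoa2, the gene of an apolipoprotein made in the yolk syncytial layer, fell from 2621 ± 327 to 1520 ± 99.7 CPM. The ribosomal protein gene rpl10 fell from 1996 ± 101 to 1134 ± 33.1 CPM, the keratin gene cyt1 from 1875 ± 155 to 1115 ± 106 CPM and vcp from 1318 ± 90.3 to 907 ± 30.3 CPM. Abundant genes higher in the mutant were cst3, a cystatin that inhibits cathepsins (340 ± 204 to 2149 ± 253 CPM), ctslb (1081 ± 103 to 1640 ± 101 CPM), hnrnpa0b (1145 ± 123 to 1674 ± 46.5 CPM), the purine synthesis gene paics (796 ± 77.7 to 1165 ± 87.9 CPM) and etf1b (610 ± 34.8 to 962 ± 17.3 CPM).

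**Figure D2:**
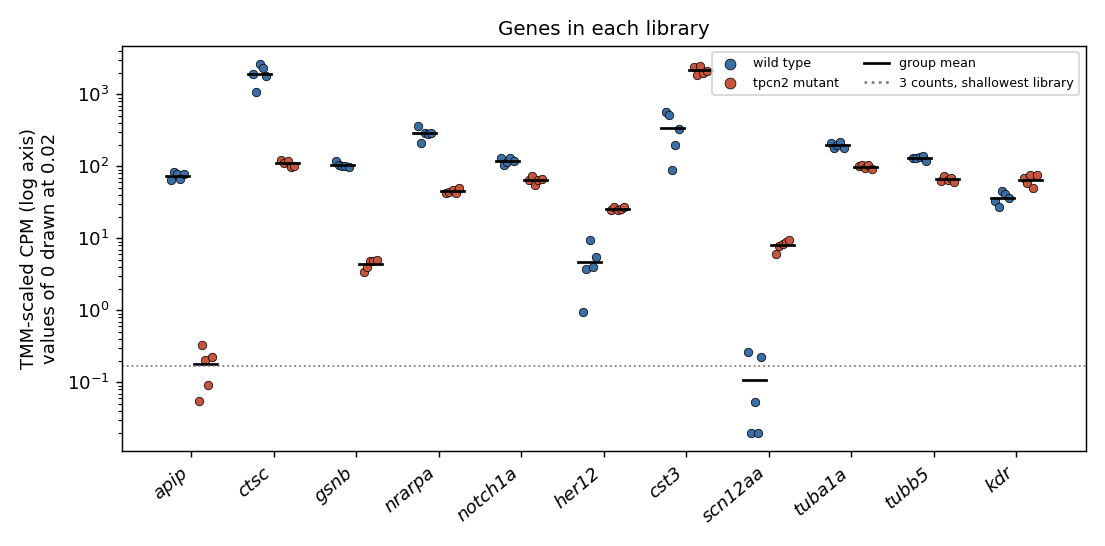
TMM-scaled CPM of 11 genes in each of the 10 libraries, on a log axis, with points for libraries, short lines for group means and values of 0 drawn at 0.02; the dotted line is 3 counts in the shallowest library. ctsc lies at 1938 ± 585 CPM in wild type and 110.6 ± 10.4 CPM in the mutant, and cst3 moves the other way.

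Neural genes were lower in the mutant. Of 34 tested members of the list of neural progenitor and neuron genes, 20 fell and 1 rose (edgeR adjusted p under 0.05, over all genes). The tubulin genes tuba1a (-0.997 ± 0.0696) and tubb5 (-0.98 ± 0.0625) were at about 0.5 times the wild-type level, and tuba1c fell by 0.59 ± 0.0427 on the log2 scale. sox2, a neural progenitor gene, was the member that rose (0.45 ± 0.222), and it did not pass under DESeq2 (adjusted p = 0.0877), with library size alone (0.0509) or in 8 of the 10 fits without 1 library. Of the tubulin genes, tuba1a and tuba1c are close paralogs of each other. camera placed the list below the other genes (adjusted p = 2.13e-05), and with an estimated correlation the adjusted p was 0.242.

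Nuclear genes of oxidative phosphorylation were lower by small amounts, 24 of 49 members falling and 2 rising, and 26 falling when adjusted over the list alone. The complex II gene sdhdb fell by 0.41 ± 0.0376, the ATP synthase gene atp5g1 by 0.35 ± 0.0355 and the cytochrome oxidase gene cox6c by 0.50 ± 0.0642 on the log2 scale, while ndufb3 (0.23) and cyc1 (0.14) rose. camera gave an adjusted p of 6.68e-04, and 0.536 with an estimated correlation.

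Endothelial genes were higher in the mutant, 9 of 20 members rising and 1 falling (10 rising when adjusted over the list alone). The VEGF receptor gene kdr rose from 36.6 ± 6.93 to 65.5 ± 11 CPM, the tight junction gene cldn5b from 4.22 ± 0.71 to 9.12 ± 0.872 CPM and sox7 from 22.2 ± 2.5 to 34.0 ± 1.84 CPM. vsg1 fell (-0.59 ± 0.22). camera gave an adjusted p of 0.00418, and 0.242 with an estimated correlation. Of 23 notochord and floor plate genes 15 rose and 4 fell (16 rising when adjusted over the list alone). The lysyl oxidase gene loxl5b (0.82 ± 0.117), sox9a (0.64 ± 0.0701) and col8a1a (0.49 ± 0.086) rose, and cav1 (-1.72 ± 0.132), the caveolin gene, col9a1a (-1.41 ± 0.261) and col2a1b (-0.52 ± 0.136) fell. camera gave an adjusted p of 0.0468 for this list, and 0.986 with an estimated correlation. The call ended without wild-type replicate 1 (0.0512), 2 (0.0891) or 3 (0.0565), without mutant replicate 1 (0.0713), 2 (0.0648) or 3 (0.0586), and with the replicate block (0.0671) and when genes of more than 1 list were left out (0.152).

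The other 25 lists did not pass camera (adjusted p under 0.05), which gave 4 lists. fry, which does not compare a list with other genes, passed 8 lists, and other splits of the 10 libraries gave up to 12 lists under camera. The counts over all genes and adjusted over the list alone were equal for 16 of the 29 lists.

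In muscle, genes of the contractile apparatus fell more often than they rose. Of 32 sarcomere and chaperone genes, 13 fell and 3 rose (14 falling when adjusted over the list alone), with acta1a, a skeletal actin gene, at 873 ± 144 CPM in wild type and 564 ± 33.0 CPM in the mutant. klhl41b (-0.62 ± 0.101) and cfl2 (-0.78 ± 0.0983) fell, and xirp1 (0.42), jph2 (0.65) and jph1a (1.42) rose. Fast fibre genes fell in 9 and rose in 1 of 24, with ckmb (muscle creatine kinase, -0.65 ± 0.132), eno3 (-0.52 ± 0.106) and pvalb2 (-1.33 ± 0.298) falling and six1a rising (0.39). Slow fibre and muscle pioneer genes fell in 7 and rose in 2 of 17, with myl10 (-0.34), tnnt1 (-0.47) and tnnt2d (-1.50) falling and prdm1a, the slow fibre regulator, rising from 102 ± 12.1 to 135 ± 3.2 CPM; tnni1al rose too (0.63 ± 0.245, adjusted p = 0.0319 by edgeR). Of 28 myogenic regulators and fusion genes 10 fell and 5 rose. The early myogenic factor myf5 rose from 38.5 ± 8.54 to 62.4 ± 4.85 CPM and fgf8a by 0.34 (log2), and jam3b, which takes part in myoblast fusion, fell from 117 ± 10.2 to 64.3 ± 4.23 CPM, with rbfox1l (-0.60) and pax7b (-0.73). None of these 4 muscle lists passed camera (adjusted p = 0.274 for sarcomere, 0.382 for fast fibre, 0.339 for slow fibre and 0.478 for myogenic genes). The shares called in either direction were 50% (sarcomere), 41.7% (fast fibre), 52.9% (slow fibre) and 53.6% (myogenic), against 42.2% of all tested genes. In the motor neuron and neuromuscular junction list, 5 of 23 fell and 4 rose, including the acetylcholine receptor subunit gene chrna1 (-0.79 ± 0.138), musk (-0.37), isl2b (-0.74), plxna3 (0.62), nrp1a (0.42) and isl2a (0.31).

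In the segmentation clock and Notch list, 6 of 36 members fell and 4 rose, 27.8% of the list against 42.2% of all tested genes. Without wild-type replicate 1, 5 fell and 7 rose, and the larger changes were those of a few genes. nrarpa, a Notch-responsive feedback gene, fell from 288 ± 53.5 to 45.2 ± 3.38 CPM (log2 fold change -2.67 ± 0.132), notch1a from 120 ± 11.8 to 65.6 ± 6.58 CPM and her15.2 from 27.1 ± 2.17 to 10.5 ± 1.4 CPM. her12, a cyclic gene of the presomitic mesoderm, rose from 4.76 ± 3.14 to 26 ± 1.27 CPM, and notch2 (0.47) and her6 (0.32) rose less. her12 and her15.2 have near-identical neighbours among which reads may be split. In the Hedgehog pathway 5 of 27 fell and 4 rose (4 and 3 when adjusted over the list alone), with shhb (0.51), ihha (0.55) and foxa2 (0.25) higher and cdon (-0.31), gli2b (-0.31) and gli2a (-0.16) lower. Of 28 Fgf, Wnt and retinoic acid feedback genes 7 rose and 5 fell, with the Fgf feedback genes dusp6 (0.53 ± 0.0546) and spry4 (0.23 ± 0.0444) higher and the retinoic acid genes aldh1a2 (-0.47 ± 0.0407), rarga (-0.52 ± 0.0679) and dhrs3a (-0.53 ± 0.0975) lower.

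Lysosomal genes moved in both directions, with 48.9% of the list called against 42.2% of all tested genes. Of 45 members 11 rose and 11 fell, and besides ctsc the decreases included scarb2 (200 ± 17.5 to 120 ± 11.4 CPM) and naga (78.6 ± 8.41 to 50.4 ± 2.56 CPM). tfeb, a transcriptional regulator of lysosomal genes, rose from 3.89 ± 0.72 to 10.5 ± 1.6 CPM, the V-ATPase accessory gene atp6ap1b from 70.33 ± 11.2 to 171 ± 14.8 CPM and cln3 from 22.7 ± 4.95 to 44.3 ± 4.15 CPM. Of 23 autophagy genes 6 fell and 2 rose (5 falling when adjusted over the list alone, and 3 without mutant replicate 1), with the receptor gene sqstm1 (0.69 ± 0.0558) and vps11 (0.43) higher and becn1 (-0.51), gabarapa (-0.52) and atg9a (-1.26) lower. Of 15 genes of two-pore channels and intracellular calcium release, 3 fell and 2 rose (2 falling when adjusted over the list alone). Besides tpcn2 these were the SERCA pump genes atp2a2a (-0.49 ± 0.136) and atp2a1 (-0.31 ± 0.15, adjusted p = 0.0483 by edgeR) below and stim1a (0.56 ± 0.136) and atp2a2b (0.24 ± 0.0615) above wild type.

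Among markers of other cell types, 6 of 23 erythroid genes fell and 4 rose. The embryonic globin genes hbbe1.1 (17.2 ± 9.33 to 3.52 ± 0.748 CPM) and hbbe2 (7.99 ± 1.98 to 3.41 ± 0.793 CPM) and urod (-0.32) fell, and blf (0.63), tal1 (0.27) and alas2 (0.32) rose; the globin genes share sequence. Of 21 cardiac genes 5 fell and 3 rose (2 rising when adjusted over the list alone, and 1 without wild-type replicate 5 or mutant replicate 1, 2 or 3), with the sarcomere genes myl7 (-0.73 ± 0.184), cmlc1 (-0.76 ± 0.191) and myh6 (-1.86 ± 0.356) lower and gata5 (0.51 ± 0.0964), tnnc1a (0.52) and gata6 (0.38 ± 0.188) higher. Of 12 myeloid genes lcp1 fell from 23.3 ± 6.4 to 4.85 ± 1.02 CPM, nccrp1 fell (-0.30) and spi1b rose (0.44). Of 21 neural crest and pigment cell genes 7 fell and 2 rose (8 falling when adjusted over the list alone), with pax7a (-0.67), twist1a (-0.33) and sox9b (-1.15) lower and snai1b (0.41) and paics higher. Of 28 epidermis and periderm genes 10 fell and 5 rose (6 rising when adjusted over the list alone), with icn (68.3 ± 20.8 to 10.6 ± 3.22 CPM) and anxa1b (161 ± 4.76 to 39.5 ± 2.94 CPM) lower and epcam (0.58), cldne (0.54) and anxa1a (0.68) higher. Of 12 hatching gland genes 3 rose and 2 fell, with he2 (1.06 ± 0.413), ctslb and xbp1 (0.20) higher and cd63 (-0.31) and tmprss13b (-1.28) lower. Of 22 genes of the yolk syncytial layer and liver-type lipoproteins 6 rose and 4 fell (7 rising when adjusted over the list alone), with serpina1 (0.74), apoa4b.2 (0.44) and apobb.1 (0.46) higher and fgg (-0.68) and apoc1l (-0.37) lower. Of 18 pronephros genes 6 rose and 2 fell, with slc9a3r1 (0.62), wt1b (0.80) and slc4a4a (0.37) higher and hnf1bb (-0.62) and atp1a1a.4 (-0.33) lower.

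Genes of cell stress and metabolism moved in both directions. The share called ran from 27.0% (cell cycle) to 55.2% (cholesterol) among the lists of this paragraph, against 42.2% of all tested genes. Of 28 p53 targets and apoptosis genes 7 rose and 3 fell, with the cell cycle inhibitor gene cdkn1a (18.3 ± 3.48 to 34.3 ± 4.62 CPM), sesn3 (167 ± 41 to 338 ± 52.7 CPM) and pmaip1 (0.78) higher and sesn2 (-0.76), casp3a (-0.36) and tp53inp1 (-0.69) lower. In the list of ER stress and the integrated stress response 11 of 39 fell and 7 rose, and 8 fell and 9 rose without wild-type replicate 1. The serine synthesis genes phgdh (242 ± 30.9 to 138 ± 2.22 CPM) and psat1 (158 ± 10.6 to 92.3 ± 8.32 CPM) and atf4a (-0.37) fell, and ddit3 (0.87), dnajb9a (1.14) and shmt2 (0.36) rose. Of 26 heat shock genes 6 fell and 3 rose, and without wild-type replicate 1 the counts were 6 and 11. With all libraries stip1 (-0.59), hspb8 (-0.61) and ahsa1a (-5.11) were lower and hsf2 (0.63), dnajb1a (0.71) and hsp90ab1 (0.18) higher. ahsa1a was at 0.16 CPM in wild-type replicate 1, as low as in the mutant libraries (0 to 0.623 CPM), against 6.27 to 13.6 CPM in the other wild-type libraries. Of 29 cholesterol synthesis and uptake genes 12 fell and 4 rose (13 falling when adjusted over the list alone), with idi1 (78.9 ± 14.4 to 46.3 ± 2.97 CPM) and hmgcs1 (-0.41) lower and the sterol transfer gene stard4 (0.688 ± 0.121 to 4.61 ± 0.726 CPM), cyp51 (0.54) and sqlea (0.45) higher. Of 13 genes of the interferon response and MHC 3 fell (b2m, irf3 and irf1a) and 2 rose (mhc1zba and ifih1). Of 37 cell cycle genes 6 rose and 4 fell (3 falling when adjusted over the list alone), and 12 rose and 4 fell without wild-type replicate 1. With all libraries mcm7 (0.37), ccne1 (0.47) and uhrf1 (0.34) were higher and rrm2 (-0.37), ccne2 (-0.28) and tyms (-0.21) lower. Median, mean and camera direction did not share 1 sign for the lysosome, Hedgehog, erythroid, myeloid, cardiac, hatching gland, heat shock, interferon and cell cycle lists. Some counts moved by at least 1.5-fold in 1 or more of the 10 fits that leave out 1 library, with these ranges. Numbers of rising genes were cardiac 1 to 3, cell cycle 5 to 12, erythroid 2 to 5, fast fibre 1 to 3, heat shock 3 to 11, interferon and MHC 1 to 3 and myeloid 1 to 4. Those of further lists were neural crest and pigment 1 to 4, neural 0 to 1, oxidative phosphorylation 1 to 2, pronephros 4 to 8, sarcomere 3 to 5, segmentation clock and Notch 3 to 7, slow fibre 1 to 2 and yolk syncytial layer 4 to 9. Numbers of falling genes were Hedgehog 3 to 6, autophagy 3 to 7, cell cycle 2 to 4, endothelial 0 to 1, hatching gland 2 to 3, interferon and MHC 2 to 3, segmentation clock and Notch 4 to 6 and calcium release 2 to 3. Of the genes named for the lists, sox2, gata6, atp2a1, tnni1al, snai1b, alas2, vsg1, tnnc1a, ifih1, irf1a, tyms and cyc1 missed the edgeR threshold when at least 1 single library was left out. Other settings also ended calls: ahsa1a and atp2a1 under limma-voom, atp2a1 with a mean CPM of at least 1, sox2 and gata6 under DESeq2, sox2 with library size alone, and snai1b, alas2 and tyms with the replicate block.

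**Figure D3:**
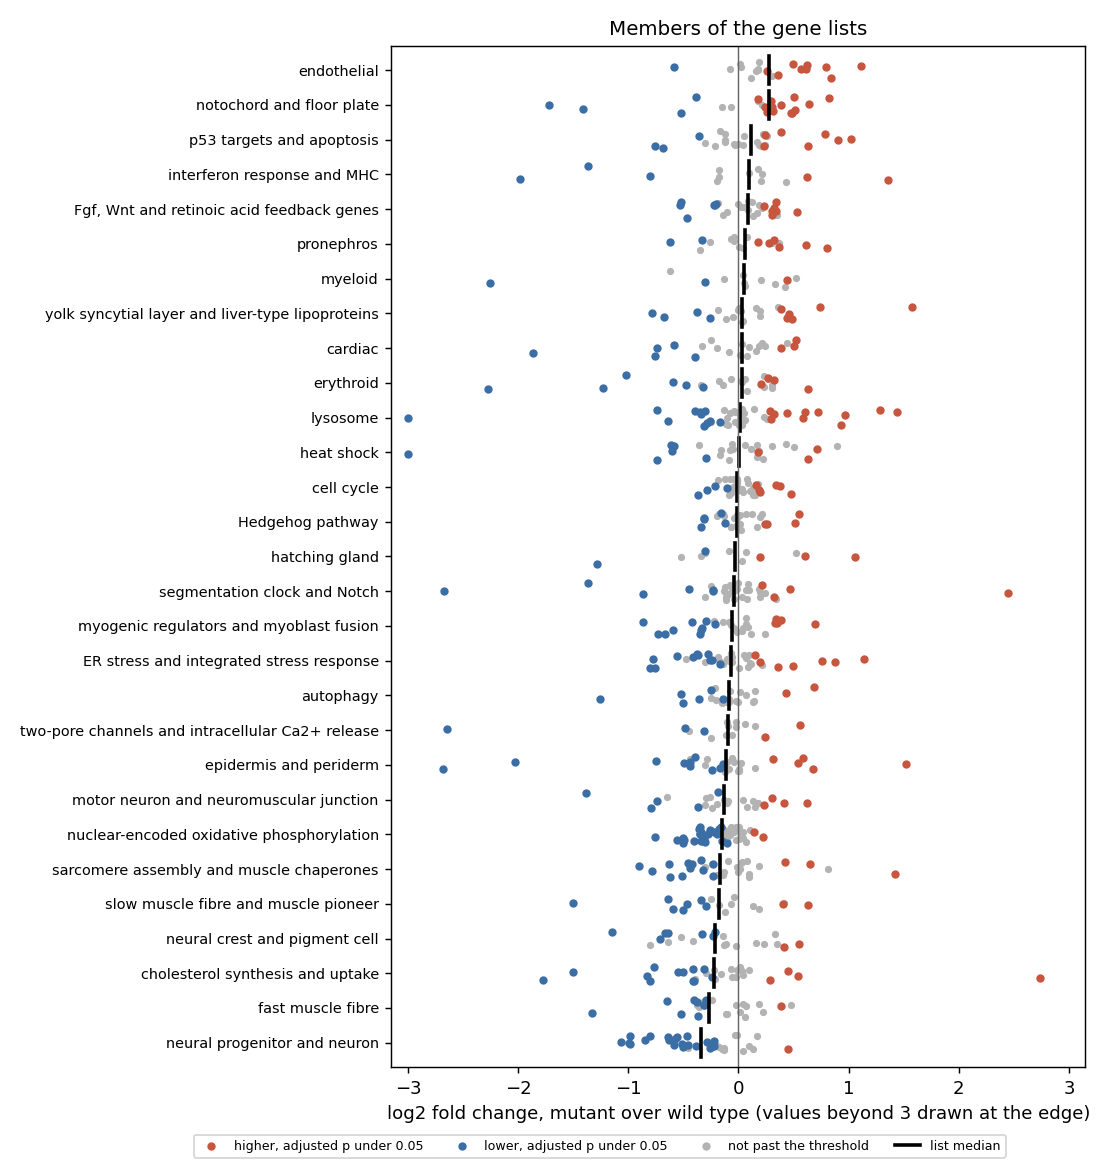
Log2 fold change, mutant over wild type, of each tested member of the 29 gene lists, with red points for members higher and blue points for members lower at adjusted p under 0.05, grey points for the rest and black lines for list medians. In the neural list 20 of 34 members are lower, and in the notochord and floor plate list 15 of 23 are higher.

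A mutant line carries the chromosome segment around the mutated gene from its founder, so called genes were placed along the chromosome of tpcn2. On chromosome 7 (gene order of the GRCz12tu assembly, without tpcn2), 213 of 571 tested genes were called (37.3%), against 4716 of 11099 elsewhere (42.5%; odds ratio 0.805, Fisher's exact test, two-sided, p = 0.015). With tpcn2 counted, shares per chromosome ran from 37.38% (chromosome 17) to 49.0%, and chromosome 7 had the second lowest at 37.41%. Among the 50 nearest tested genes on each side, 7 of 100 changed at least 2-fold, against 644 of 11570 elsewhere (odds ratio 1.28, Fisher's exact test, p = 0.508). They were dhcr7 (-1.50), which makes cholesterol, bco1 (1.90), gcshb (-1.81), penkb (2.99), sdcbp (-1.32), spata6l (1.34) and zgc:173587 (1.05), all named after their values were seen.

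**Figure D4:**
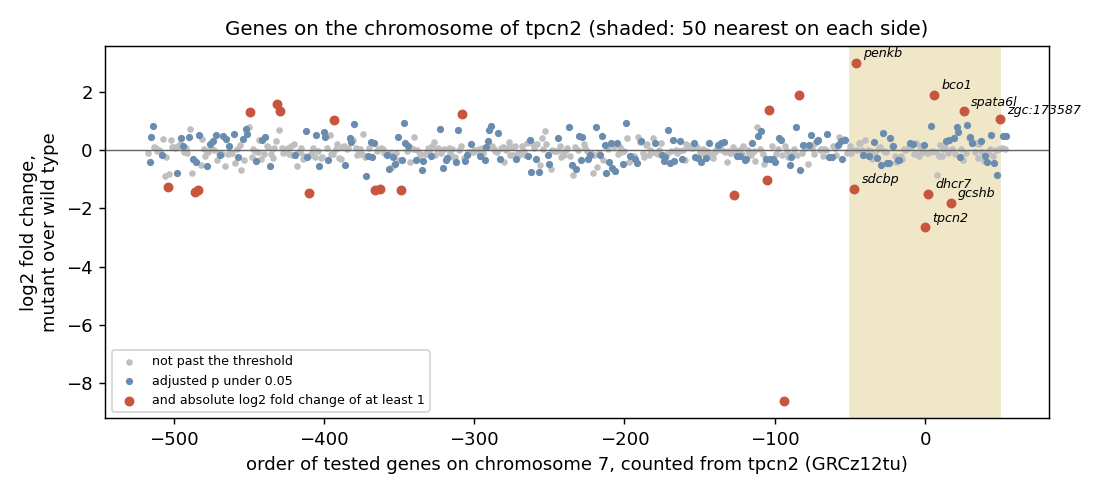
Log2 fold change, mutant over wild type, of tested genes on chromosome 7 in gene order counted from tpcn2 (GRCz12tu), with red points for genes called with at least a 2-fold change, blue for other called genes and grey for the rest. In the shaded stretch of the 50 nearest genes on each side, 7 genes besides tpcn2 changed at least 2-fold; apip is the point at -8.61.

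A total of 5308 genes in the authors' deposited table passed an adjusted p of 0.05, 2607 higher and 2701 lower in the mutant. Of these, 4966 passed with the same sign in the edgeR fit, and none of the 5142 tested in both had the opposite sign. The authors' deposited table gives tpcn2 a log2 fold change of -2.44. Sizes of change were less alike than signs for some genes. Log2 fold changes correlated at 0.962 across genes (Pearson) but differed by up to 5.90. cyp4v7 was at -2.78 in the authors' deposited table and -8.68 in the edgeR fit, and apip at -6.95 and -8.61. The cause of these differences was not tested. At an adjusted p of 0.01, the authors' deposited table has 3944 genes, of which 3336 passed in the edgeR fit with the same sign.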

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

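In groups of 5 libraries, 16 of 362 tests found 1 library far from the other 4 (Dixon's ratio above 0.71), and about 18.1 would be expected by chance. The number of flags was thus no more than chance would give, which does not settle whether any single flag is due to chance. No value was tested for differing effects between tissues or times, since the design has 1 stage.

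In wild-type replicate 1, etf1b was at 549 CPM (others 615 to 633), scarb2 at 169 CPM (201 to 212) and ahsa1a at 0.16 CPM (6.27 to 13.6). In wild-type replicate 2, fut9d was at 38.0 CPM (24.4 to 28.0), b2m at 1.33 CPM (3.44 to 4.36), irf3 at 0.428 CPM (1.5 to 2.04) and cyc1 at 277 CPM (307 to 315). In wild-type replicate 4, notch2 was at 86.0 CPM (70.5 to 75.0) and cldn5b at 5.46 CPM (3.78 to 4.18), and in wild-type replicate 5 tubb5 was at 117 CPM (131 to 137).

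In mutant replicate 1, ihha was at 10.3 CPM (8.7 to 9.18) and cav1 at 10.6 CPM (13.5 to 14.02). In mutant replicate 2, sc:d217 was at 0.0479 CPM, 1 read, with 0 in the others. In mutant replicate 3, anxa1b was at 34.4 CPM (39.6 to 41.7), in mutant replicate 4 myf5 at 53.8 CPM (63.8 to 65.7), and in mutant replicate 5 hbbe2 at 2.06 CPM (3.42 to 4.11).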

How the results depend on the processing

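tpcn2 kept its direction and passed under every alternative run, with log2 fold changes from -2.71 to -2.49 when single libraries were left out. Counts of higher genes ran from 2146 to 2611 and of lower genes from 2317 to 2701 without single libraries, and gene lists from 3 to 5. An adjusted p under 0.01 left 1576 higher genes, and glmTreat 89 higher and 128 lower genes, by their construction. An estimated correlation gave 0 lists (2 at an unadjusted p under 0.05). For the 4 lists called at the preset of 0.01 the estimates were 0.0609 (neural), 0.0815 (oxidative phosphorylation), 0.0329 (endothelial) and 0.113 (notochord and floor plate). The correlation was the only setting that differed between these camera runs, so the 4 calls rest on a preset below the estimates. fry, which does not compare a list with other genes, gave 8. Of the 178 called genes chosen by the naming rule, none reversed, and 13 missed the threshold in some alternative (69 of 3022 values). Same-numbered libraries deviated from their group means with correlations of -0.0615 to 0.0745. Those numbered 2 and 3 were each other's closest match between the groups, and those numbered 1, 4 and 5 were not. A batch shared by number was therefore neither shown nor excluded. With the replicate block 2378 genes were higher and 2451 lower, 4643 of the main calls were shared, and 3 lists passed. The odds ratio for the 50 nearest genes on each side of tpcn2 (chosen after the data were examined) was 1.28 for 2-fold changes, where the chromosome's was 0.733, and 0.837 at an adjusted p under 0.05, on the chromosome's side of 1; the cause was not tested. Lists with no call also turned direction: lysosome under fry (adjusted p = 0.877) and without single libraries (0.799 to 0.99), myeloid under fry (0.447), with a mean CPM of at least 1 (0.971) and without single libraries (0.695 to 0.979), cardiac with a mean CPM of at least 1 (0.971) and without single libraries (0.847 to 0.993), interferon with a mean CPM of at least 1 (0.971) and without single libraries (0.81 to 0.979), heat shock without a filter (0.969) and without single libraries (0.73 to 0.979), erythroid (0.895 to 0.99) and hatching gland (0.906 to 0.979) without single libraries. With scaling by library size alone the median of all genes was -0.00818, and -0.00114 with TMM.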

Other observations

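Of the tests in this part, the comparison of neuron with progenitor genes, the division of the late list, the genes nearest to tpcn2 and the splits of medians were chosen after the results were seen, and so was the margin of 1 SD asked of the count of adjacent pairs.

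apip, whose reads nearly vanished in the mutant, lies on chromosome 7 with tpcn2, 94 tested genes away (gene order of GRCz12tu). Only 54 tested genes lie beyond tpcn2 on its other side. Of 54 tested early regulators outside the fixed lists, 17 were called higher in the mutant and 5 lower. Those higher include the ventral genes vent (0.70) and vox (0.35), bmp7a (0.95), chd (0.60), the apelin receptor gene aplnra (0.37) and snai1a (0.49), and those lower include lft1 (-0.76), lhx1b (-0.49), hoxd4a (-0.42) and zic2a (-0.31). Of 54 late genes 13 were called lower and 7 higher. The lower ones include the brain creatine kinase gene ckbb (-0.78), mllt11 (-0.60), aldocb (-0.71), stxbp1a (-0.50) and cntn2 (-0.90), but the lens genes lim2.1 (1.92) and crygn2 (1.05), cp (1.89) and cldnk (1.11) rose. These genes were named after their values were seen.

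The real grouping called 5011 genes and the other splits at most 11, so 1 of 100 splits, the real one, gave as many. Every other split mixed the genotypes, which puts their difference into the spread within groups. The low counts of those splits follow from that difference and do not measure how many calls chance would give. They also say nothing of clutch or strain, which cannot be told apart from genotype here. For the number of lists past camera, 55 of 100 splits gave at least as many as the real 4, with up to 12 in another split. Those splits mixed the genotypes as well, so they do not measure how many lists chance would give, and chance was not excluded. In the medians of list members over all 126 splits, the real grouping was the most extreme for 6 of 29 lists: neural, endothelial, notochord and floor plate, epidermis, cholesterol and oxidative phosphorylation. The same limit holds for that ranking.

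Neural genes were lower in the mutant, and so were 13 of 32 sarcomere genes (camera adjusted p = 0.274) and 2 globin genes, while myf5 and blf were higher and pax7a (-0.67) and pax7b (-0.73) lower. An earlier stage of the mutant embryos could bring these changes about, but they are selected members of lists that moved in both directions. The erythroid list had a median of 0.029 (camera adjusted p = 0.966), with alas2 higher, and the slow fibre regulator prdm1a was higher too. Endothelial genes rose in 9 and fell in 1 of 20, and notochord and floor plate genes rose in 15 and fell in 4 of 23. Outside the fixed lists 54 late genes lay below 54 early genes (medians -0.11 and 0.14, difference -0.25, permutation test over genes, p = 0.00132). Of 126 splits of the libraries 2 gave a difference as large. The late list holds 21 neuronal genes (median -0.35), which restate the neural decrease; the other 33 had a median of 0.0062, a difference of -0.138 from the early genes (permutation test, p = 0.106), and the 22 outside neurons, glia, brain and eye sensory cells a median of 0.0501, a difference of -0.0938 (p = 0.417), so neither median lay below 0 and an earlier stage stays open. Fewer neural cells of every kind could lower both kinds of neural gene alike. The 19 neuron genes had a median of -0.56 and the 15 progenitor genes -0.18, a difference of -0.38 (permutation test over genes, p = 0.0029). In whole embryos, progenitor genes also expressed outside neural tissue would fall less, and pax2a is in the pronephros list too. The difference therefore cannot decide this, and fewer neural cells or a loss of neurons alone stay open. The neural list still passed camera without wild-type replicate 1 (adjusted p = 0.000145), which argues against that library as the cause, although with an estimated correlation and all libraries it did not pass (adjusted p = 0.242). A delay from the mutation, staging differences between clutches and strain background stay open too, because the design holds 1 mutant line at 1 stage.

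Genes changed at least 2-fold may mark haplotypes in which the 2 lines differ. 48 adjacent pairs of such genes were seen against a permuted range of 27 to 49 (mean 37.6, SD 5.88, permutation p = 0.0509), and 45 pairs without neighbours of the same symbol stem against 25 to 47 (permutation p = 0.067). Linked variants and reads shared between tandem copies cannot be told apart from a genotype effect here, since 48 lies inside the permuted range by less than 1 SD and variants of the lines were not analysed here. ahsa1a, near absent in all mutant libraries and in wild-type replicate 1 (0.16 CPM), also varied within wild type.

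Changed genes near tpcn2 may belong to a linked haplotype around the mutated locus. The odds ratio for a 2-fold change among the 50 nearest genes on each side was 1.28 (Fisher's exact test, p = 0.508), above 1 but within chance, so the 7 such genes cannot be told apart from the genome's average.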
